A study of Mus musculus with 2 samples.

How the data were processed

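Gene expression was measured by RNA sequencing in mouse eosinophils that had been grown from bone marrow and then co-cultured. Per the labels' protocols, marrow cells of wild-type C57BL/6 mice received stem cell factor and FLT3 ligand at 100 ng/ml each from the start to day 4, and then interleukin-5 at 10 ng/ml. Cells were collected on day 14, when eosinophils typically made up over 92% of them. After the co-culture, eosinophils from 3 wells were pooled into 1 sample per condition, and total RNA was extracted from eosinophils isolated from the wells. How they were separated from the other cells of the co-culture is not given in the sources used here. Libraries were made from oligo-dT-selected RNA with a protocol that keeps the strand, and were sequenced on a DNBSEQ instrument.

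There were 2 libraries in 2 groups, named here as their titles name them: LTbR FRC and B Cell FRC. LTbR is the usual abbreviation of the lymphotoxin beta receptor, and FRC of the fibroblastic reticular cell, a stromal cell of lymph nodes. The labels do not say whether the receptor was stimulated, blocked or deleted, or whether B cells were present in the wells with the eosinophils. With 1 library per group there are no replicates, so no difference has a replicate check, and no p-value or standard deviation between libraries was computed.

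The authors deposited one table of FPKM values and one table of TPM values, per the file headers. FPKM is the number of fragments per kilobase of transcript per 1000000 fragments, and the deposited TPM values are transcript shares scaled to the same total in each library. Per the submitters' processing notes, HISAT, Bowtie2 and the genome build GRCm39 were used, with no versions and no roles given. The counting tool, the annotation release, the use of strand in counting and any filter are not given in the sources used here. Within a library the deposited TPM was a constant multiple of the deposited FPKM, 1.56 for LTbR FRC and 1.37 for B Cell FRC, over genes above 20 FPKM. The choice between the units therefore rescales one library against the other, and with a filter and pseudocount of 1 in either unit it changes those as well. Columns were matched to samples by name, since the samples stand in opposite order in the 2 tables. Column names carry a number after the condition whose meaning is not given.

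Each table listed 74693 features, of which 22173 were typed as mRNA, and 17440 of those held values. The other 4733 mRNA features and the 52520 features of other types had empty cells and were not analysed here. Immunoglobulin constant regions, Xist, the mitochondrially encoded genes, Ccl11, Ccl19 and Ccl21a were among them. Of the genes with values, 1742 were listed at 0 in both libraries. The files hold no counts, and values are rounded to 2 decimals, so whole reads could not be recovered. Depth was estimated from genes with a single annotated transcript of 800 to 1500 nucleotides, with lengths from the GENCODE M21 annotation of GRCm38. That build differs from the authors' build, so the annotation served for lengths only and no coordinates are given. The most frequent low value of FPKM times length in kilobases lay between 0.07 and 0.08 in both libraries, for 16 of 84 genes with LTbR FRC and 12 of 114 with B Cell FRC. If this step is 1 fragment, each library held about 12500000 to 14300000 fragments, and genes near 1 TPM rest on few of them.

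For each gene the log2 ratio was log2 of TPM plus a pseudocount of 1 in the B Cell FRC library over the same quantity in the LTbR FRC library. Positive values are higher in the B Cell FRC library. The pseudocount understates the differences of low genes. Genes with a mean of at least 1 TPM over both libraries were compared, which left 11806. A gene was counted as higher or lower when the ratio reached 2-fold. For each gene list, the median ratio of its measured members was set against 10000 random lists of the same size, matched in 20 bins of mean expression. A list was said to stand apart when its percentile was under 2.5 or over 97.5 and at least 5 members were measured. These percentiles are a description of these libraries, not a test of the conditions.

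The design, the 22 pathway lists, the 14 cell type lists, the thresholds and the rule for named genes were fixed before the data were examined. The rule took, among genes with a given name and a mean of at least 5 TPM, the 12 with the highest and the 12 with the lowest ratio. For each list it added up to 4 measured members by size of ratio and any other member at 2-fold or more. A fixed set of eosinophil identity and question genes was added whatever their values, which gave 208 genes in all. Genes named outside the rule are marked as such, and some genes the rule took are not reported here. Members of near-identical families (Ear1, Ear2 and Ear6; Hspa1a and Hspa1b; the Bcl2a1 genes; Csf2rb and Csf2rb2; the H2 genes) can share reads, and their single values are uncertain.

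Alternatives fixed in advance were pseudocounts of 0.1 and 5, no filter, a filter of 10 TPM, FPKM in place of TPM, centring on the median ratio of genes with at least 10 TPM, removal of the 100 most abundant genes, named genes only, thresholds of 1.5-fold and 4-fold, 10 expression bins, and the mean in place of the median. Centring on the median of the eosinophil surface and granule lists was added after seeing the data, and so was a list of ribosomal proteins. Held-out lists of B-cell, stromal and myeloid genes were written after the main results were seen and before their own values were looked at.

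The calculation was tested on simulated libraries of 13000000 fragments built from the 11806 genes of the B Cell FRC against LTbR FRC comparison, with 200 changed genes. It recovered 89 of 100 simulated 3-fold changes and 99 of 100 simulated 4-fold changes past the 2-fold threshold. It called 1 of 11606 unchanged genes, and 11 of 200 random lists fell outside the percentile range. The simulation covers counting error only. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.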

Results

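Eosinophil transcriptomes were compared between 2 co-culture conditions, named LTbR FRC and B Cell FRC, with 1 library each from 3 pooled wells. The stated purpose of the study was to learn how stromal cells affect eosinophil gene expression. Both libraries carried very high levels of eosinophil granule transcripts: Prg2, which encodes major basic protein, took up 5.30% of all TPM with LTbR FRC and 3.77% with B Cell FRC. The 18 eosinophil surface and lineage genes summed to 9385 and 6003 TPM. The 17 measured monocyte and macrophage genes summed to more, 13332 and 8336 TPM. Such sums do not give cell shares, but both libraries held high levels of transcripts listed for other myeloid cells. The 100 most abundant genes held 37.5% and 39.6% of TPM. Depth was roughly estimated at 12500000 to 14300000 fragments in each library, if the most frequent low value of FPKM times length stands for 1 fragment. Across the 11806 genes compared, log2(TPM + 1) of the libraries correlated with a Pearson r of 0.94, a value across genes, which are not independent replicates.

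The B Cell FRC library held high levels of B-cell transcripts that were mostly low with LTbR FRC. It also held much higher levels of MHC class II transcripts, which were present with LTbR FRC too, and moderately higher levels of type I interferon response genes. The LTbR FRC library held higher levels of collagen and other stromal transcripts, of several neutrophil- and monocyte-attracting chemokines, and of matrix proteases and their inhibitors. All 18 eosinophil surface genes were lower with B Cell FRC, with log2 ratios from -0.97 to -0.38 and a median of -0.61. Monocyte and macrophage genes had a median of -0.72, with 15 of 17 below 0 and ratios from -1.22 to 0.08. At the 2-fold threshold, 583 genes were higher and 634 lower in the B Cell FRC library, and 10589 genes (89.7%) lay within 2-fold. The higher genes held 1.5% of TPM with LTbR FRC and 4.61% with B Cell FRC, and the lower genes 2.53% and 0.914%.

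The split between higher and lower genes depended on the unit and the centring. With a main split of 47.9% higher, FPKM gave 727 higher and 294 lower of 11376 genes (71.2% higher), where the pseudocount and the filter of 1 were in FPKM and so differed from those in TPM too, and centring on genes of at least 10 TPM gave 706 and 466 (60.2% higher). Centring on the eosinophil lists, chosen after seeing the data, gave 2009 and 133 (93.8% higher). The median ratio of all genes was -0.14 on the TPM scale, 0.04 on the FPKM scale and 0.44 after centring on the eosinophil lists.

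**Figure D1:**
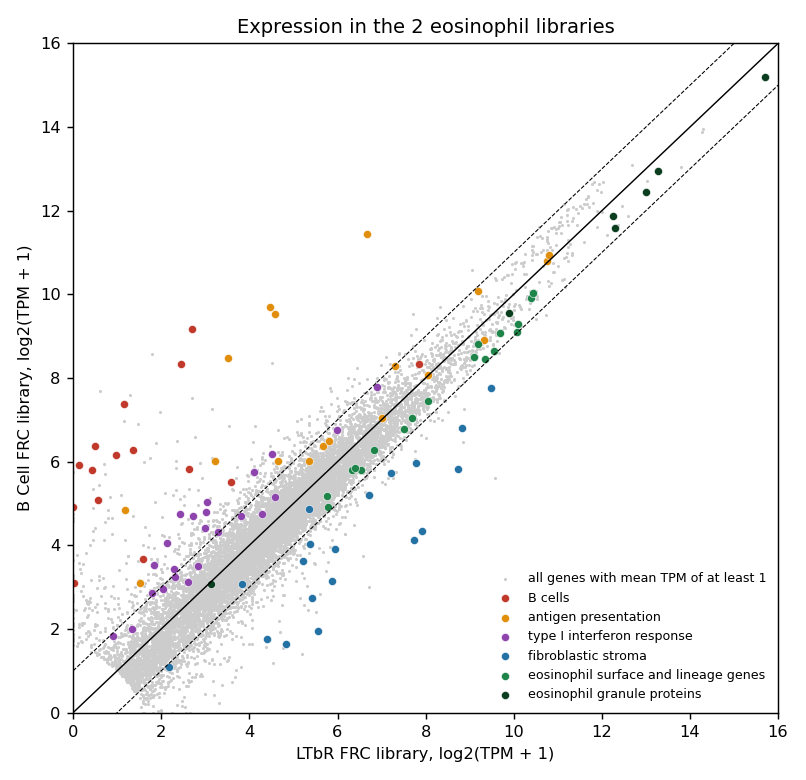
Each point is a gene, placed by log2(TPM + 1) in the LTbR FRC library (x axis) and in the B Cell FRC library (y axis); the solid line marks equal values and the dashed lines 2-fold differences. Of 11806 genes, 583 lie above and 634 below the 2-fold lines.

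Among the 12 genes with the highest ratios, most encode proteins of B cells or antibody-secreting cells. Cd79a (gene 12518) and Cd79b (gene 15985), the signalling chains of the B-cell receptor, stood at 5.52 and 4.42 TPM with LTbR FRC and at 577 and 320 TPM with B Cell FRC, log2 ratios of 6.47 and 5.89. Pax5 (gene 18507), the transcription factor of B-cell identity, stood at 0.34 and 54.7 TPM (5.38). Jchain (gene 16069), which joins antibody chains into polymers, had the highest ratio, 7.08, from 0.52 and 204 TPM. Ly6d (gene 17068) followed at 6.79, and Mzb1 (gene 69816), a chaperone of antibody secretion, at 6.32. Further genes of this group were Pou2af1 (gene 18985) at 5.89, the BAFF receptor gene Tnfrsf13c (gene 72049) at 5.80, the low-affinity IgE receptor gene Fcer2a (gene 14128) at 5.79, and the lymph node homing receptor gene Ccr7 (gene 12775) at 5.44. Alpl (gene 11647), which encodes an alkaline phosphatase, was listed at 0 with LTbR FRC and at 52.7 TPM with B Cell FRC.

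Of 15 measured genes of the B-cell list, 14 were at least 2-fold higher with B Cell FRC and none lower, with a median ratio of 4.92 (percentile 100). Ms4a1, which encodes CD20, stood at 0.95 and 70.5 TPM. Of 6 measured plasma cell genes, 4 were at least 2-fold higher and the other 2 lay below 0 (median 3.22, percentile 100). Among these 6 genes Irf4 stood at 0.50 and 42.4 TPM. Sdc1, which encodes syndecan-1 and is also made by stromal and epithelial cells, was lower, at 70.9 and 24.7 TPM. With no filter the plasma cell median fell to 1.5955 over 7 genes (percentile 100), so its size depended on the filter. Of the sex-linked list 3 genes passed the filter, too few for a percentile, and these 3 were listed at 0 with LTbR FRC. Eif2s3y stood at 24.1 TPM with B Cell FRC, Ddx3y at 8.45 and Kdm5d at 4.61, all of them genes of the Y chromosome.

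Antigen presentation genes were higher with B Cell FRC in 8 of 18 measured members, and none was 2-fold lower (median 0.92, percentile 100). The MHC class II genes led the group. H2-Ab1 stood at 21.1 and 826 TPM (5.23), H2-Aa at 22.8 and 735 TPM (4.95), and Cd74, the class II invariant chain, at 101 and 2784 TPM (4.77). Ciita, the master regulator of class II genes, stood at 1.25 and 27.6 TPM. Higher in the same library was the B-cell list, at a median of 4.92. With 1 library per group, a link between these lists could not be tested.

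All 23 measured type I interferon response genes had ratios above 0, and 12 were at least 2-fold higher with B Cell FRC (median 1.02, percentile 100). Oasl1 stood at 4.34 and 25.7 TPM (2.32), Zbp1, a sensor of nucleic acids, at 5.58 and 25.1 TPM (1.99), Irf7, a transcription factor of interferon induction, at 16.2 and 53.2 TPM (1.66), and the ubiquitin-like Isg15 at 21.8 and 71.5 TPM (1.67). The B-cell list, at a median of 4.92, was higher in the same library.

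The 12 lowest ratios belonged mostly to genes of the extracellular matrix. Mgp (gene 17313), which encodes matrix Gla protein, stood at 759 TPM with LTbR FRC and 47.5 TPM with B Cell FRC (-3.97). The type I collagen genes Col1a1 (gene 12842) and Col1a2 (gene 12843) had ratios of -3.58 and -3.61, the first from 240 and 19.2 TPM. Col3a1 (gene 12825) had a ratio of -3.61, Col15a1 (gene 12819) of -3.71, Col6a3 (gene 12835) of -3.19 and the fibrillin gene Fbn1 (gene 14118) of -3.17. Aldh1a3 (gene 56847), a retinoic acid-producing enzyme, had a ratio of -3.79, and Mfap5 (gene 50530), Cdh11 (gene 12552), Ltbp2 (gene 16997) and the proteoglycan gene Bgn (gene 12111) ratios of -3.34, -3.23, -3.10 and -2.91. Of 19 measured genes of the fibroblastic stroma list, 17 were at least 2-fold lower with B Cell FRC (median -2.00, percentile 0).

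Matrix proteases and inhibitors were at least 2-fold lower in 6 of 16 members (median -0.84, percentile 0), and in 1 of 16 after centring on the eosinophil lists (median -0.26). The inhibitor gene Timp1 stood at 460 and 87.2 TPM (-2.38), and Mmp12, a macrophage elastase, at 1707 and 726 TPM (-1.23). Endothelial genes had a median of -0.77 (percentile 0.14), with 1 of 9 at least 2-fold lower, Cldn5, at 4.14 and 0.14 TPM. The stromal median of -2.00 and the monocyte and macrophage median of -0.72 lay in the same direction as both groups.

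All 18 eosinophil surface and lineage genes lay below 0 (median -0.61, percentile 0), and none reached 2-fold. Siglecf, the surface lectin used to identify mouse eosinophils, stood at 206 and 131 TPM (-0.64), the eotaxin receptor gene Ccr3 at 92.3 and 54.9 TPM (-0.74), and the interleukin-5 receptor gene Il5ra at 52.9 and 35.1 TPM (-0.58). Granule protein genes had a median of -0.38 (percentile 11.4), with Prg2 at 53025 and 37745 TPM (-0.49), Epx, the eosinophil peroxidase, at 5014 and 3094 TPM (-0.70), and Ear1 at 8148 and 5541 TPM (-0.56). Genes of monocytes and macrophages had a median of -0.72 (percentile 0, 2 of 17 at least 2-fold lower), and those of mast cells and basophils of -0.55 (percentile 1.04, none of 9 at 2-fold). After centring on the eosinophil lists the medians were -0.03 for surface genes, 0.20 for granule genes, -0.14 for monocytes and macrophages and 0.02 for mast cells and basophils, so the directions of the granule and mast cell lists turned, and those of Prg2 (0.088) and Ear1 (0.022) with them.

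**Figure D2:**
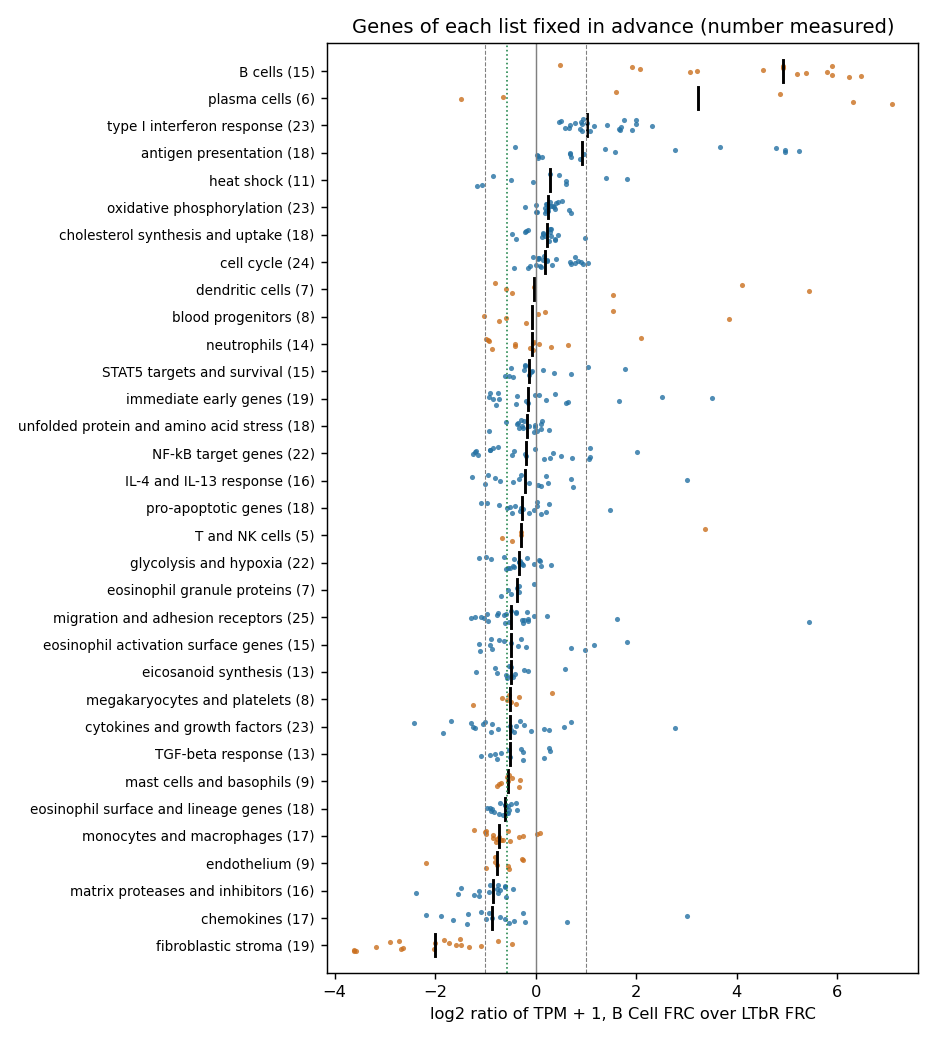
Each dot is a gene, placed by its log2 ratio of B Cell FRC over LTbR FRC (TPM + 1), within its list (blue, pathways; orange, cell types); black bars are medians, dashed lines 2-fold differences and the green dotted line the median of the eosinophil lists, -0.58. The B-cell list lies highest by median, 4.92, among lists with at least 5 measured members, and the fibroblastic stroma list lowest, -2.00.

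Chemokine genes had a median of -0.86 (percentile 0). Of 17 measured, 6 were at least 2-fold lower with B Cell FRC and 1 was higher, against 3 lower and 2 higher after centring on the eosinophil lists (median -0.28), where Ccl2 (-0.78) no longer reached 2-fold. The neutrophil-attracting Cxcl2 and Cxcl1 stood at 54.5 and 11.2 TPM (-2.18) and at 43.1 and 11.0 TPM (-1.88), and the monocyte-attracting Ccl2 and Ccl7 at 328 and 127 TPM (-1.36) and at 151 and 47.5 TPM (-1.65). Ccl22, a chemokine that recruits T cells, was the exception, at 4.01 and 39.0 TPM (3.0). The eotaxin gene Ccl24 was at 0.29 TPM with LTbR FRC and listed at 0 with B Cell FRC. Stromal genes, at a median of -2.00, monocyte and macrophage genes, at -0.72, and eosinophil surface genes, at -0.61, were lower in the same library.

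Cytokine and growth factor genes had a median of -0.52 (percentile 0.27), with 8 of 23 at least 2-fold lower and 1 higher. After centring on the eosinophil lists, 3 were lower and 3 higher, and the median turned to 0.062. Csf3, which encodes the neutrophil growth factor G-CSF, stood at 15.8 and 2.11 TPM (-2.43), Il1a at 15.6 and 3.61 TPM (-1.85), Vegfa at 25.6 and 7.23 TPM (-1.69) and Tnf at 113 and 48.3 TPM (-1.21). Lta, which encodes lymphotoxin alpha, was higher with B Cell FRC, at 0.32 and 7.96 TPM (2.76). Ltb, a ligand chain of the lymphotoxin beta receptor, stood at 46.3 and 68.9 TPM (0.56), and Ltbr at 45.8 and 26.5 TPM (-0.77). Tnfsf13, which encodes the B-cell and plasma cell factor APRIL, stood at 6.22 and 2.04 TPM (-1.25), and Tnfsf13b, which encodes BAFF, at 0.98 and 0.33 TPM. Il4 stood at 5.27 and 4.90 TPM (-0.09), Il13 at 1.70 and 0.60 TPM (-0.75), Il6 at 15.4 and 10.7 TPM (-0.49), and Tgfb1 at 455 and 318 TPM (-0.52). Stromal genes, at a median of -2.00, were lower in the same library as Csf3, Il1a and Vegfa, and B-cell genes, at 4.92, higher in the same library as Lta. After centring on the eosinophil lists Il4 stood at 0.49, Il6 at 0.091 and Tgfb1 at 0.062.

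Activation surface genes had a median of -0.50 (percentile 0.99), migration and adhesion receptors of -0.50 (percentile 0.12), TGF-beta response genes of -0.52 (percentile 0.68) and eicosanoid synthesis genes of -0.50 (percentile 1.01). These 4 medians turned above 0 after centring on the eosinophil lists. With the mean of members, activation genes (percentile 23.2) and migration receptors (percentile 10.9) no longer stood apart, nor did TGF-beta genes with a pseudocount of 5 (percentile 5.68), no filter (3.04) or a filter of 10 TPM (2.95). At 2-fold, 2 of 15 activation genes were higher and 2 lower. Il2ra stood at 0.90 and 5.65 TPM and the co-stimulatory receptor gene Cd40 at 14.8 and 34.1 TPM, while Cd80 stood at 19.8 and 8.57 TPM. Cd274, which encodes the checkpoint ligand PD-L1, stood at 48.3 and 25.9 TPM (-0.87). Of 25 migration and adhesion genes, 4 were lower, among them the complement receptor gene C5ar1 (-1.29), and 2 were higher, Ccr7 and Gpr183 (1.62). Stromal genes (-2.00) and monocyte and macrophage genes (-0.72) lay in the same direction as these 4 medians, and B-cell genes (4.92) in that of Ccr7, Gpr183, Cd40 and Il2ra. Cxcr4 stood at 280 and 251 TPM (-0.16) and Ccr1 at 129 and 84.2 TPM (-0.61), and centring on the eosinophil lists moved Cxcr4 to 0.42.

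Several pathway lists that did not stand apart held genes going both ways. NF-kB target genes had a median of -0.20 (percentile 22), with 4 of 22 higher, among them Traf1 (2.02), and 4 lower, among them Ptgs2 (-1.19). Immediate early genes had a median of -0.16 (percentile 38.3) and a mean of 0.18, with 3 of 19 higher, among them the phosphatase gene Dusp2 (3.51) and the orphan receptor gene Nr4a1 (2.5). STAT5 target and survival genes had a median of -0.14 (percentile 41.1) and a mean of 0.06, with Myc at 26.6 and 93.3 TPM (1.77). Heat shock genes had a median of 0.28 (percentile 96.3), with the mitochondrial chaperones Hspe1 (1.82) and Hspd1 (1.41) higher and Hspa1a (-1.17) and Hspa1b (-1.06) lower. The IL-4 and IL-13 response list had a median of -0.21, pro-apoptotic genes of -0.27, unfolded protein and amino acid stress genes of -0.18, and glycolysis and hypoxia genes of -0.33 (percentile 4.15). The glycolysis list stood apart with a filter of 10 TPM (percentile 0.96), without the 100 most abundant genes (1.02) and with the mean of members (0.62), and the heat shock list with a filter of 10 TPM (percentile 99.0). Centring on the eosinophil lists turned the lists of this paragraph with medians below 0 above 0, and FPKM turned IL-4 and IL-13 response, STAT5 target, unfolded protein and immediate early genes.

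Counts at 2-fold in other lists also moved after centring on the eosinophil lists. Of the stromal list 13 genes were then lower, against 17. Higher genes then numbered 23 of 23 in the interferon list, against 12, and 13 of 18 in the antigen presentation list, against 8. Activation genes then stood at 4 higher and none lower, migration receptors at 2 and none, NF-kB targets at 6 and none, heat shock genes at 5 and none, immediate early genes at 5 and none, cell cycle genes at 8 and none, oxidative phosphorylation genes at 4 and none, and cholesterol genes at 2 and none. IL-4 and IL-13 response genes then stood at 3 higher and none lower, against 1 and 2, and STAT5 targets at 3 and none, against 2 and none.

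Oxidative phosphorylation genes had a median of 0.25 (percentile 98.5), with 22 of 23 above 0 and none at 2-fold. Cholesterol genes had a median of 0.23 (percentile 98.7) and cell cycle genes of 0.19 (percentile 98.1), where the replication licensing gene Mcm3 stood at 68.9 and 144 TPM (1.05). Oxidative phosphorylation (percentile 95.6) and cholesterol genes (percentile 87.5) no longer stood apart with the mean of members, nor did cell cycle genes with a pseudocount of 5 (percentile 97.4). The B-cell list, at 4.92, was higher in the same library as these 3 lists. Among other cell types, neutrophil genes had a median of -0.08, dendritic cell genes of -0.03, T and NK cell genes of -0.29, megakaryocyte and platelet genes of -0.51 and blood progenitor genes of -0.08, and none of these stood apart by its median. These 5 medians turned above 0 after centring on the eosinophil lists, those of neutrophils, dendritic cells and progenitors also after centring on genes of at least 10 TPM, that of neutrophils also on the FPKM scale, and that of dendritic cells also with no filter and without the 100 most abundant genes. The dendritic cell list had a mean of 1.31 and stood apart by it (percentile 100), with Ccr7 (5.44) and Cd83 (4.10), which B cells also express, the highest. The T and NK list had a mean of 0.33, with Lck at 3.36, and the progenitor list a mean of 0.38, with Ly6a at 3.84. Erythroid genes had a median of 0.42 over 3 measured members.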

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

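Centring on the eosinophil lists was chosen after seeing the data, and the other alternatives were planned. No library could be left out, because each group has 1. No paired analysis was possible because each group holds 1 library and nothing was tested. At 2-fold, higher and lower genes numbered 583 and 634. Lower genes numbered 1000 with a pseudocount of 0.1 and 294 with FPKM. Higher and lower genes numbered 332 and 189 with a pseudocount of 5, 374 and 267 with a mean of at least 10 TPM, and 2009 and 133 after centring on the eosinophil lists. The 2009 genes included all 583, and the 634 included all 133. A 1.5-fold threshold gave 1396 and 2209 genes, and a 4-fold threshold 145 and 61, through the threshold itself. The remaining 10 counts stayed within 1.5 times.

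Across the lists that stand apart and the alternatives, 194 medians kept their direction and their side of the percentile limits, 8 lost the limits and 6 turned. After centring on the eosinophil lists, medians turned to 0.082 for activation surface genes and for migration and adhesion receptors, 0.062 for cytokines, 0.058 for TGF-beta response, 0.081 for eicosanoid synthesis and 0.025 for mast cells and basophils; a shift of all ratios by the same amount is what this alternative does. With the mean of members, activation genes (-0.20), migration receptors (-0.23), oxidative phosphorylation (0.27) and cholesterol genes (0.16) no longer stood apart. Cell cycle (0.15) and TGF-beta genes (-0.33) no longer did with a pseudocount of 5, nor did TGF-beta genes with no filter (-0.41) or at 10 TPM (-0.41). Lists that did not stand apart passed the limits in 5 comparisons: 3 of glycolysis and hypoxia, 1 of heat shock and, with the mean of members, 1 of dendritic cell genes. The cause was not tested. Of the named genes, 1491 comparisons stayed within 0.5 log2 and 302 moved further, with none past 2-fold turning. Many of these outcomes were fixed by the setting, so the tally is no measure of stability. A changed filter leaves a gene's ratio as it is. Centring on genes of at least 10 TPM takes a constant of -0.10 off every ratio, so those comparisons had to stay within 0.5. Centring on the eosinophil lists takes off -0.58, so its 205 comparisons had to move and none past 2-fold could turn. The B-cell, stroma, interferon and chemokine lists kept their direction in every alternative run. Genes listed near 1 TPM rest on few fragments, which limits what these counts can show for low genes.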

Other observations

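The test on the B-cell list fixed in advance, the tests on Y-linked genes, on eosinophils switching on B-cell genes, on chemokines and on eosinophil lineage genes alone, and the list of ribosomal proteins were chosen after the results were seen. All 77 ribosomal protein genes measured had ratios above 0, with a median of 0.59 (percentile 100), and 2 were at least 2-fold higher with B Cell FRC, against 65 after centring on the eosinophil lists (median 1.17). Together they held 143233 TPM with LTbR FRC and 218044 TPM with B Cell FRC. The B-cell list, with 14 of 15 genes at least 2-fold higher and a median of 4.92, was higher in the same library. As single values, picked after they were seen and so no evidence on a gene group, Npm1 stood at 532 and 1538 TPM (1.53), Ncl at 318 and 825 TPM (1.37), and Fbl, the methyltransferase of ribosomal RNA, at 86.6 and 301 TPM (1.79). Myc, which drives ribosome production, stood at 26.6 and 93.3 TPM.

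The following single genes outside the fixed lists were picked because their values were high with B Cell FRC, so they add no evidence on a group. Cxcr5, the receptor that guides B cells into follicles, stood at 0.62 and 60.8 TPM, Ccr6 at 0.64 and 51.4 TPM, the B-lineage transcription factor gene Spib at 2.70 and 86.7 TPM, and Il4i1, an amino acid oxidase induced by interleukin-4, at 2.34 and 66.9 TPM. The Y-linked gene Uty, a member of the fixed sex-linked list under the filter, was listed at 0 and at 1.59 TPM.

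B-cell genes were high in the B Cell FRC library, and RNA of B cells carried over from the co-culture is a candidate source: the labels mention isolation of the eosinophils but not the method, and a sort on an eosinophil marker would remove most B cells. A test written in advance asked whether a held-out list of 20 B-cell genes had a median ratio of at least 1, with a value under 0.5 counting against B-cell RNA; the median was 0.47, so the test missed its bound, and it was 1.05 after centring on the eosinophil lists, a scaling chosen after seeing the data. That bound was a poor choice, because 15 of the 20 genes stood at 10 TPM or more with LTbR FRC (median 50.4 TPM, against 1.21 TPM for the fixed B-cell list), where a small share of B cells would be hidden, and 7 of the 20 were at least 2-fold higher; the replacement reading, that 14 of 15 genes of the fixed list were at least 2-fold higher, was chosen afterwards and would also hold if eosinophils had switched on those genes. All 4 Y-linked genes (Eif2s3y, Ddx3y, Kdm5d and Uty) were at 0 in one library and above 1 TPM in the other. This argues for RNA from an animal of the other sex and against eosinophils of the same animals as the source of that signal. The Y-linked genes reached 18.9% (Eif2s3y), 6.54% (Ddx3y), 12.8% (Kdm5d) and 12.8% (Uty) of the level of their X-linked partners. These percentages do not give a share of RNA from that animal. No male reference was used here, and the X-linked partners were read from the whole library. Whether the Y-linked RNA came from B cells, stroma or other marrow stays open, and the 14 higher genes leave it open as well: B-cell RNA and expression by eosinophils cannot be told apart in bulk RNA.

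Stromal genes were high in the LTbR FRC library, and a larger share of stromal RNA in the sample is a candidate explanation. A held-out list of stromal genes had a median of -1.51 over 22 measured genes, 19 of them at least 2-fold lower with B Cell FRC, past the bound of -1 set in advance, but -0.93 with 6 lower after centring on the eosinophil lists, short of that bound. The most abundant genes of the fixed stromal list with LTbR FRC were Fn1 (718 TPM), Sparc (450 TPM) and Bgn (425 TPM). Less stromal RNA alone may also lower the chemokines. Their median of -0.86 lay above the middle range of the stromal ratios (-2.81 to -1.50) and below the highest (-0.47). This reading was chosen after the results were seen and sets a list median against single genes, so it cannot decide. Monocyte and macrophage genes, at a median of -0.72, were lower in the same library too. Less stromal RNA cannot be told apart from lower expression by eosinophils, and the part of other cells stays open. An effect of the condition on the stroma itself was not tested.

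Eosinophil surface genes were all lower with B Cell FRC, with ratios from -0.97 to -0.38, and a smaller share of RNA from the eosinophil culture could account for this. A held-out list of 23 myeloid genes, not specific to eosinophils, had a median of -0.59, inside the range set in advance, and all 23 were below 0. After centring on the eosinophil lists, which removes the eosinophil shift itself, the median was -0.01, outside that range. The list was also read against lower expression of eosinophil lineage genes alone. That reading was chosen after the results were seen, so it is no independent test. The median of -0.59 shows only that, on the TPM scale, genes not specific to eosinophils were lower too. The ribosomal protein genes were higher instead, so part of the shift may follow from the fixed total of TPM. Neutrophil genes (median -0.08, 10 of 14 below 0) and dendritic cell genes (median -0.03, 4 of 7 below 0) did not stand apart by their medians. The highest dendritic cell genes were Ccr7 and Cd83, which B cells also express. These medians therefore do not show that the genes of those lists escaped the fall. An effect of the co-culture on the myeloid genes that were lower stays open.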
